A study of Mus musculus with 12 samples.

How the data were processed

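Gene expression was measured on 12 dual-colour Agilent mouse arrays in cells released from the caecum of NMRI mice, either left uninfected or infected orally with 1500 oocysts of Eimeria falciformis, at 24 h or 144 h after infection. Per the labels, caecal pieces were treated with DTT, the cells that came off in EDTA were passed through a strainer and lysed, total RNA was purified, and it was labelled with a linear amplification kit for low RNA input. The sample titles call the material intestinal epithelial cells; no sort that would remove other cell types is described. Each array carried infected RNA in one dye and uninfected RNA of the same time point in the other, and a dye-swapped partner array carried the reverse. The sample descriptions number 3 experiments per time point, and each number stands for a slide with its own scan and its own version of the Feature Extraction software, 9.5.1.1, 9.5.3.1 and 10.5.1.1. The slide of experiment 1 is titled as rehybridized. How many animals stand behind each RNA, and whether both arrays of a dye-swap pair share the same extracts, is not given in the sources used here. The p-values therefore measure the spread between these samples, which may be technical rather than the spread between mice.

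Per the file headers, each scanner file gives spot and local background signals as intensity values, with processed intensity values that the scanner software had detrended, background-subtracted and dye-normalized. The deposited ratio of each spot is a log10 value computed by the same software. The deposited files also hold a unit other than intensity or log10, namely marks of 0 or 1 for spots well above background, saturated, or marked as outliers by the scanner software. The authors' table of all arrays holds log10 ratios that equal the ratios in the scanner files after turning them to infected over uninfected, with a largest difference of 0.00497 and a median of 0 on every array. That largest difference belongs to the 24 h array of experiment 2 with infected RNA in Cy5, whose values had been rounded and in which 47 gene names differ from the other arrays.

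Each array held 45018 spots, of which 1639 were control spots, and 41174 gene probes were used. Of these probes, 22951 took their gene symbol from the reference gene table through an accession, 18223 kept the name in the scanner files, and 8412 had only an accession or clone as a name. The mean signals were corrected with the normexp method (offset 50) and normalized by loess within each array (span 0.3) in limma 3.58.1 under R 4.3.3, with version 1.17.8 of data.table. Log2 ratios were turned to infected over uninfected, and the 2 arrays of a dye-swap pair were averaged, so that n = 3 ratios stood for each time point. Spots marked as outliers by the scanner software were left out, 102 to 212 per array. Probes were kept if they were well above background on all 6 arrays of at least 1 of the 4 RNA groups, which left 20310 probes. The brightest probe stood for each gene, which gave 14498 genes, 19 of them with a missing value in some ratio. A channel showed between 43.0% and 76.0% of the gene probes well above background and between 0 and 27 saturated probes. The number of arrays limits the precision.

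All 6 ratios entered 1 limma model with a mean for each time point, 4 residual degrees of freedom and 3.93 prior degrees of freedom. Infected was compared with uninfected at 24 h and at 144 h, and the response at 144 h with that at 24 h. A gene passed the test at a two-sided Benjamini-Hochberg adjusted p under 0.05. Of the 36 gene lists written beforehand, 35 with at least 5 measured genes were tested with camera from limma (preset correlation 0.01, two-sided, adjusted over the lists), and again with an estimated correlation and with fry. For each list, the members that passed were counted among all genes tested and also adjusted over the list alone. The gene lists, tests, thresholds, alternatives and the rule for named genes were fixed before the data were examined. The rule named the 10 largest changes in each direction that passed with the same sign on all 6 arrays, up to 4 members with the smallest p of each list described, and Ido1, Irf1, Igtp, Irgm1, Iigp1 and Gbp2 always. Some genes that the rule or a list names are not reported here. For the difference between the times it named 5 genes in each direction. Names that are only clone or accession identifiers were passed over. Malat1 was added after the value of Xist was seen, with its test written before its own result was. Ifng, Xist, other genes outside the rule and families of genes that share a symbol stem were chosen after their values were seen, and the text says so at each. A gene whose uninfected signal was not well above background on any array is given as "at least" a fold, computed against the background of those arrays.

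The experiment numbers were read as pairing the time points by slide. The correlation across genes between the deviations of the same experiment number was 0.37, 0.23 and -0.06, so the pairing was tried as an alternative and is given only where it changes a call. Further alternatives covered other background corrections and normalizations, filters, thresholds, 1 dye orientation alone, a model of all 12 arrays, the authors' log10 ratios, and leaving out each experiment. Leaving out only the 24 h ratio of experiment 2 or of experiment 1 was chosen after seeing the data, because the dye-swapped arrays or the probe positions set those ratios apart. The procedure was tested on simulated data of 14413 genes, each drawn independently with the spread of its residuals. With changes of log2 1 or 2 added, it recovered 52% or 91% of the changed genes at 24 h, 42% or 91% at 144 h, and 23% or 78% for the difference. Both times were drawn with the same spread per gene, and each size of change had 100 genes at each time. The recoveries therefore do not compare the power at 24 h with that at 144 h. Unchanged genes made up 5.30%, 2.92% and 5.16% of the calls. With no gene changed, 0 lists passed. A T cell list raised by log2 1 had an adjusted p of 8.11e-43 while 0 other lists passed. Simulated genes were not correlated with each other, so these list results cannot show how the list tests treat correlated genes. Confidence intervals of list medians used 10000 bootstrap resamples of genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Erythroid genes, with 3 measured, were not tested as a list.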

Results

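Infection of the mouse caecum by Eimeria falciformis, a coccidian parasite that multiplies in intestinal epithelial cells, was followed at 2 time points on 12 dual-colour arrays, with 3 dye-swapped experiments at 24 h and 3 at 144 h. Each array compared RNA of infected with RNA of uninfected caecal cells, so values below are log2 ratios of infected over uninfected, as means of n = 3 experiments. The standard error (SE) is that of the limma fit, which pools the spread over both times and moderates it across genes, so it can be smaller than the spread of the 3 experiments at 1 time. Between 43.0% and 76.0% of the 41174 gene probes were well above background in a channel. The 2 dye-swapped arrays of an experiment correlated across genes with r = 0.90, -0.11 and 0.53 in experiments 1, 2 and 3 at 24 h, and with 0.94, 0.66 and 0.95 at 144 h. Genes are not independent replicates. Across 3870 genes with probes at different distances from the 3′ end, the ratio at the probe nearer the 3′ end minus that at the farther probe had a mean of -0.41, -0.12 and 0.00 at 24 h and -0.30, -0.05 and -0.13 at 144 h, so experiment 1 stood apart at both times and its ratios depended on where a probe lies. Whether this comes from the RNA or from the slide was not tested, and leaving out experiment 1 was tried as an alternative.

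The comparison at 24 h asked which host genes respond soon after the parasite arrives, with interferon-gamma-regulated pathways as the interest that the series title names. Genes that interferon-gamma induces were already strongly raised. Iigp1, an immunity-related GTPase that acts on the vacuoles of intracellular parasites, was 46.6-fold higher (log2 5.54, SE 0.30, adjusted p = 0.000136), and Ido1, the rate-limiting enzyme of the kynurenine pathway, was 29.9-fold higher (log2 4.90, SE 0.24, adjusted p = 0.000104). In total 100 of 14498 genes passed the test, 93 higher and 7 lower, and 99 of them had the same sign on all 6 arrays.

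The genes with the largest rises at 24 h were effectors and regulators of the interferon response. Cxcl10, Cxcl9 and Cxcl11, ligands of the lymphocyte receptor Cxcr3, rose by log2 4.95 (SE 0.33), 3.67 (SE 0.19) and 3.53 (SE 0.35), with adjusted p = 0.000397, 0.000104 and 0.00268. The immunity-related GTPases Tgtp1 and Igtp rose by 4.73 and 4.37, and the guanylate-binding proteins Gbp2 and Gbp3 by 3.90 and 3.64. Socs1, a feedback inhibitor of cytokine signalling, rose by 3.94 (SE 0.14, adjusted p = 2.51e-05). Irgm1, a regulatory GTPase of the same family as Iigp1, rose by 2.51 (SE 0.17, adjusted p = 0.000408), and Irf1, an interferon-induced transcription factor, by 1.66 (SE 0.16, adjusted p = 0.0022). Ifng itself, chosen after its value was seen, rose by 1.87 (SE 0.31, adjusted p = 0.0437) and was higher on 6 of 6 arrays. It rose by 3.20 with the scanner software's processed signals and by 1.17 at another probe. Ifng did not pass without background correction (adjusted p = 0.0632), with median centring (0.0765), with no filter on dim probes (0.159), with each time point alone (0.158) or on arrays with infected RNA in Cy3 alone (0.0978). Without experiment 2, Irf1 at 1.62 (adjusted p = 0.134), Cxcl11 at 3.40 (0.112) and Ifng at 1.63 (0.539) no longer passed. Without experiment 3, Irf1 at 1.57 (0.0595) and Ifng at 1.72 (0.187) did not pass. Another probe of Tgtp1 gave 1.70.

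On build mm7, which the array design uses, the probe of Ido1 (gene 15930) lay on chromosome 8 from 23370259 to 23370318. The probes of Irf1 (gene 16362), Igtp (gene 16145) and Irgm1 (gene 15944) lay on chromosome 11 at 53733970 to 53734029, 58288970 to 58289029 and 48822320 to 48822379. Those of Iigp1 (gene 60440) and Gbp2 (gene 14469) lay on chromosome 18 from 60781938 to 60781997 and on chromosome 3 from 142530694 to 142530753.

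Interferon lists rose as groups at 24 h. All 6 measured immunity-related GTPases rose, also 6 when adjusted over the list alone, with a median of 3.81 (camera adjusted p = 1.66e-21, and adjusted p = 0.0924 with an estimated correlation). Of 9 guanylate-binding proteins, GTPases that attack pathogen vacuoles, 5 rose, or 7 when adjusted over the list alone, with a median of 1.34 (adjusted p = 6.19e-13, and adjusted p = 0.0924 with an estimated correlation). Among 20 other targets and signalling genes of interferon-gamma, 11 rose, or 14 with 1 lower when adjusted over the list alone, with a median of 1.67 (adjusted p = 1.24e-19, and adjusted p = 0.0924 with an estimated correlation). Among 31 genes stimulated by type I interferon, 9 rose, or 25 when adjusted over the list alone, with a median of 1.05 (adjusted p = 1.06e-23, and adjusted p = 0.121 with an estimated correlation). Members included the antiviral genes Ifit2 at 2.90 (SE 0.23, or 1.85 at another probe), Isg15 at 2.45 (SE 0.21) and Zbp1 at 2.14 (SE 0.15).

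Antigen presentation genes rose at the same time. Of 13 genes of the MHC class II pathway, 7 rose, also 7 when adjusted over the list alone, with a median of 2.00 (adjusted p = 5.37e-13, and adjusted p = 0.105 with an estimated correlation). Ciita, the master regulator of class II genes, counted above among the interferon-gamma genes, rose by 3.24 (SE 0.16). Within the list, the peptide-exchange subunit H2-DMa rose by 2.69 (SE 0.15) and the class II chains H2-Eb1 and H2-Aa by 2.40 and 2.36. Of 21 genes of MHC class I and peptide loading, 6 rose, or 10 when adjusted over the list alone, with a median of 0.59 (adjusted p = 7.76e-16, and adjusted p = 0.191 with an estimated correlation). The immunoproteasome subunits Psmb9 and Psmb8 rose by 2.75 and 2.14 and the peptide transporter Tap1 by 2.40. Of 11 tryptophan and kynurenine genes, 2 rose, Ido1 and Wars, or 3 when adjusted over the list alone, with a median of 0.11 (adjusted p = 0.00286, and adjusted p = 0.126 with an estimated correlation). Wars, the tryptophanyl-tRNA synthetase that interferon-gamma induces, rose by 2.98 (SE 0.20). The median of this list was -0.06 with median centring and 0.24 without experiment 1.

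**Figure D1:**
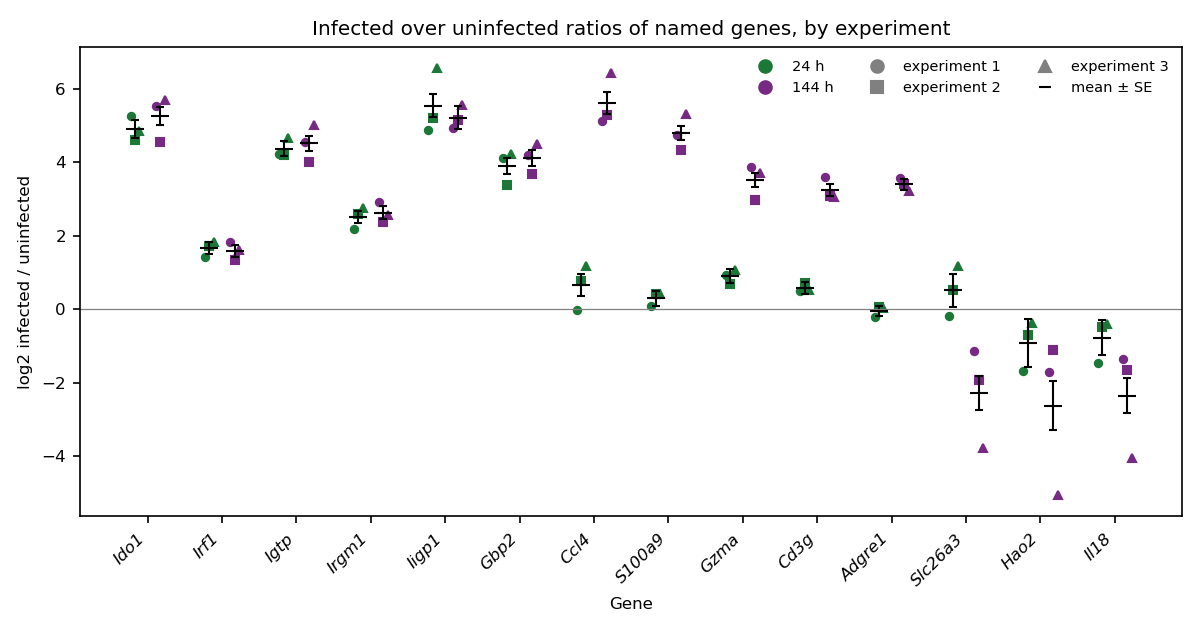
Log2 ratio of infected over uninfected for 14 named genes at 24 h and 144 h, with a circle, square and triangle for experiments 1, 2 and 3 and a bar for the mean ± SE of the fit (n = 3). Ido1 and Iigp1 stood near their 144 h values already at 24 h, with means of 4.90 and 5.54 against 5.26 and 5.22.

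Markers of immune cells were slightly raised at 24 h. Of 19 genes of cytotoxic lymphocytes and NK cells, 3 rose, or 6 when adjusted over the list alone, with a median of 0.08 and a mean of 0.40 (adjusted p = 7.62e-05, and adjusted p = 0.106 with an estimated correlation). These were the killing protease Gzmb at 1.63 (SE 0.17), the granule protein Nkg7 at 1.23 and the receptor chain Il2rb at 1.01; without experiment 2 none of the 3 passed (adjusted p = 0.140, 0.221 and 0.687). Nkg7 and Il2rb also did not pass without experiment 1 (0.116 and 0.126) or experiment 3 (0.238 and 0.213), and Il2rb did not with experiments as blocks (0.0823). With median centring none of the 3 passed (0.0696, 0.0823 and 0.0836). Lists of T cells (median 0.23), B and plasma cells (0.48) and macrophages, monocytes and dendritic cells (0.11) passed as groups with adjusted p = 0.000637, 0.00726 and 0.0162, and adjusted p = 0.364, 0.573 and 0.489 with an estimated correlation. No member of these 3 lists passed the limma test on its own; adjusted over the list alone the counts were 1, 0 and 0, and at an unadjusted p under 0.05 they were 5, 2 and 4. Without experiment 3 the B cell list, at 0.22, and the macrophage list, at 0.11, no longer passed (adjusted p = 0.200 and 0.0951), nor did the macrophage list without experiment 2, at 0.09 (0.0528). The median of the B cell list was 0.31 without experiment 2.

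Epithelial and metabolic lists had small medians at 24 h. The list of 34 xenobiotic and drug metabolism genes was lower as a group, with a median of -0.44. The limma test passed 0 members, or 4 lower when adjusted over the list alone and 11 at an unadjusted p under 0.05 (camera adjusted p = 2.03e-05, and adjusted p = 0.441 with an estimated correlation). Goblet cell genes had a median of -0.34 over 17 genes, with 0 members past the limma test, 0 when adjusted over the list alone and 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.00529, and adjusted p = 0.341 with an estimated correlation). Without experiment 3 the median was -0.19 and the list did not pass (adjusted p = 0.163). The S phase list was higher as a group, with a median of 0.29 over 26 genes, though of -0.01 with median centring. The limma test passed 0 of its members, also 0 when adjusted over the list alone and 10 at an unadjusted p under 0.05 (camera adjusted p = 9.86e-05, and adjusted p = 0.534 with an estimated correlation). In the list of 28 cell death and inflammasome genes only Tnfsf10, the death ligand TRAIL, rose (2.26, SE 0.16), or 4 genes when adjusted over the list alone, with a median of 0.15 (adjusted p = 0.00746, and adjusted p = 0.516 with an estimated correlation). The median of that list was -0.19 with median centring and 0.08 without experiment 2, and the list did not pass without experiment 3, at 0.18 (adjusted p = 0.246).

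A few genes fell at 24 h. Nrp2, a co-receptor for semaphorins and VEGF, fell by 1.35 (SE 0.21, adjusted p = 0.0386), and Cldn8, a sealing claudin of tight junctions, fell by 1.32 (SE 0.20, adjusted p = 0.0318). Arhgap24 fell by 1.22 and Angpt2, a ligand of the endothelial receptor Tie2, fell by 1.12. Msrb2, a mitochondrial methionine sulfoxide reductase, was 0.466-fold its uninfected level (adjusted p = 0.0386). Pdcd4, an inhibitor of translation, also fell, by 0.97, and so did a gene with only a locus name, both named after their values were seen. Without experiment 2 the adjusted p of the 5 genes named by the rule was 0.629, 0.415, 0.514, 0.431 and 0.726, so none passed. All but Nrp2 also failed without experiment 3 (0.118, 0.125, 0.159 and 0.236), and all but Msrb2 without experiment 1 (0.153, 0.113, 0.135 and 0.106). With experiments as blocks Nrp2, Arhgap24 and Angpt2 did not pass (0.0682, 0.0539 and 0.0517). With the processed signals Nrp2, Cldn8, Arhgap24 and Angpt2 did not (0.0515, 0.187, 0.0527 and 0.141). With each time point alone none of the 5 passed. No gene at all passed as lower at 24 h without experiment 2 or with each time point alone. Only Msrb2 did so without experiment 1, and only Nrp2 without experiment 3. Pdcd4 and the gene with a locus name therefore did not pass as lower in any of these settings. Without the whole of experiment 2 the number of genes past the test at 24 h was 37, and without experiment 3 it was 58. With median centring, which set the median of all genes at -0.26, the split was 61 higher and 24 lower.

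The remaining lists did not pass at 24 h. Their medians were 0.04 for chemokines and inflammatory cytokines, 0.12 for antimicrobial defence, -0.11 for enteroendocrine cells, 0.06 for tuft cells, -0.17 for crypt base cells, 0.01 for G2 and mitosis and -0.09 for surface colonocytes. They were 0.06 for cholesterol synthesis, -0.14 for fatty acid oxidation, -0.12 for lipogenesis, -0.04 for glycolysis, -0.09 for oxidative phosphorylation, -0.09 for endoplasmic reticulum stress, -0.19 for p53 targets and 0.00 for immediate early genes. For adhesion and junctions the median was -0.13, for neutrophils and mast cells -0.10, for fibroblasts, muscle and endothelium 0.18, for pancreatic and gastric genes 0.07 and for Paneth cells 0.13.

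At 144 h the comparison asked which host genes differ once the infection is established, and the response was broad. Inflammatory and interferon-induced genes were the most raised. Ccl4, a chemokine that attracts monocytes and T cells, was 49.1-fold higher (log2 5.62, SE 0.30, adjusted p = 1.37e-05), Ido1 38.4-fold (5.26, SE 0.24, adjusted p = 1.1e-05) and Iigp1 37.2-fold (5.22, SE 0.30, adjusted p = 1.67e-05), while genes of the absorptive epithelium and of drug metabolism fell. Of 14498 genes, 3912 passed the test, 2338 higher and 1574 lower, and 1891 of them changed at least 2-fold, 1409 higher and 482 lower. The same sign on all 6 arrays was seen for 3598 of the 3912.

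The largest rises at 144 h included genes of inflammatory myeloid cells. Clec7a, the β-glucan receptor dectin-1, rose by 5.08 (SE 0.20), Spp1, the cytokine osteopontin, by 4.89 (SE 0.19), S100a9, a subunit of calprotectin, by 4.80 (SE 0.20) and Irg1, the enzyme that makes itaconate, by 4.75 (SE 0.19), each with adjusted p = 1.1e-05. Ifi202b, an interferon-inducible DNA-binding protein, rose by 5.37 (SE 0.25), with uninfected signal well above background on 4 of 6 arrays, and Ccl8, a monocyte chemokine, by 4.67 (SE 0.22). Ifng, chosen after its value was seen, rose by 4.60 (SE 0.31, adjusted p = 2.66e-05), or by 3.68 at another probe. With the processed signals Clec7a, Spp1 and Ifi202b rose by 6.44, 5.76 and 7.11. Igtp, Gbp2, Irgm1 and Irf1 rose by 4.52, 4.12, 2.62 and 1.58.

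Interferon lists were raised at 144 h as at 24 h. All 6 immunity-related GTPases rose, also 6 when adjusted over the list alone, with a median of 3.77 (adjusted p = 1.25e-08, and adjusted p = 0.112 with an estimated correlation). All 9 guanylate-binding proteins rose, also 9 when adjusted over the list alone, with a median of 2.77 (adjusted p = 3.41e-10, and adjusted p = 0.105 with an estimated correlation). Of the 20 other interferon-gamma genes, 16 rose, or 17 when adjusted over the list alone, with a median of 2.43 (adjusted p = 1.22e-11, and adjusted p = 0.105 with an estimated correlation). Of 31 type I interferon genes, 26 rose, or 28 when adjusted over the list alone, with a median of 1.52 (adjusted p = 3.31e-13, and adjusted p = 0.155 with an estimated correlation). MHC class II genes rose in 11 of 13 cases, also 11 when adjusted over the list alone, with a median of 2.19 (adjusted p = 4.27e-09, and adjusted p = 0.109 with an estimated correlation). MHC class I genes rose in 19 of 21 cases, also 19 when adjusted over the list alone, with a median of 1.26 (adjusted p = 2.5e-09, and adjusted p = 0.189 with an estimated correlation). Examples were Gbp3 at 4.67, Socs1 at 3.83, Usp18, an enzyme that removes Isg15 from proteins, at 3.16, H2-Aa at 2.87 and Psmb9 at 2.59.

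Defence and signalling groups rose too. Of 25 chemokines and inflammatory cytokines, 20 rose and 2 fell, or 20 and 3 when adjusted over the list alone, with a median of 1.89 (adjusted p = 8.99e-10, and adjusted p = 0.0363 with an estimated correlation). Il1b, the inflammatory cytokine interleukin-1 beta, rose by 4.39, while Il18 fell by 2.36 and Il15, named after its value was seen, fell by 1.07 but did not pass without experiments 2 or 3 (adjusted p = 0.0704 and 0.0835). Without experiment 3 the value of Il18 was -1.52. Of 25 antimicrobial and mucosal defence genes, 10 rose and 3 fell, or 12 and 6 when adjusted over the list alone, with a median of 0.71 (adjusted p = 0.0149, and adjusted p = 0.315 with an estimated correlation) and of 0.43 without experiment 1. With the strict filter on dim probes it did not pass (adjusted p = 0.548). The protease inhibitor Slpi and the lysozyme Lyz1 each rose by 3.20. Pigr, the receptor that carries IgA into the lumen, fell by 1.82, or by 1.08 without experiment 3. Retnlb, a goblet cell protein, fell by 0.91 and the oxidase Nox1 fell by 0.81, but neither passed without experiment 2 (adjusted p = 0.119 and 0.0517) or experiment 3 (0.141 and 0.0715). With the processed signals Nox1 fell by 1.66. Pigr, Retnlb and Nox1 were named after their values were seen. Of 11 tryptophan and kynurenine genes, 6 rose and 2 fell, with the same counts when adjusted over the list alone, and the median was 0.60 (adjusted p = 0.0348, and adjusted p = 0.18 with an estimated correlation). Ido1, Wars at 2.68, the amino acid transporter Slc7a5 at 1.28 and Qprt, which makes a NAD precursor from quinolinate, at 0.98, or 1.85 with the processed signals, rose. The kynurenine aminotransferases Kyat1 and Kyat3, named after their values were seen, fell by 1.08 and 0.71, but did not pass without experiment 2 (0.0984 and 0.0729) or experiment 3 (0.0754 and 0.212), nor did Kyat3 without experiment 1 (0.0578). This list did not pass with experiments as blocks (adjusted p = 0.0528), with the strict filter (0.0660) or without experiment 1 (0.0639, median 0.75).

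Markers of leukocytes were raised at 144 h in every lineage tested. Of 19 cytotoxic lymphocyte and NK cell genes, 18 rose, or 19 when adjusted over the list alone, with a median of 2.30 (adjusted p = 2.48e-14, and adjusted p = 0.0363 with an estimated correlation), among them the granzymes Gzma at 3.51 and Gzmb at 3.43. Of 18 T cell genes, 16 rose, or 16 with 2 lower when adjusted over the list alone, with a median of 2.51 (adjusted p = 1.22e-11, and adjusted p = 0.105 with an estimated correlation), among them Cd5 at 3.52 and Cd3g, a chain of the T cell receptor complex, at 3.25. Of 21 macrophage, monocyte and dendritic cell genes, 19 rose, or 20 when adjusted over the list alone, with a median of 2.72 (adjusted p = 2.33e-14, and adjusted p = 0.105 with an estimated correlation), among them the macrophage marker Adgre1 at 3.40, or 4.25 with the processed signals, and the Fc receptor subunit Fcer1g at 3.57. Of 11 neutrophil, mast cell and eosinophil genes, 10 rose, or 11 when adjusted over the list alone, with a median of 1.99 (adjusted p = 1.48e-09, and adjusted p = 0.132 with an estimated correlation), among them S100a8, the partner of S100a9, at 3.52 and the mast cell chymase Cma1 at 2.88, or 1.92 at another probe. Of 14 B and plasma cell genes, 11 rose, or 12 when adjusted over the list alone, with a median of 1.48 (adjusted p = 6.57e-05, and adjusted p = 0.316 with an estimated correlation), among them the co-activator Pou2af1 at 2.93 and the immunoglobulin mu chain Igh-6 at 2.66. Of 13 fibroblast, muscle and endothelium genes, 10 rose, or 11 when adjusted over the list alone, with a median of 1.01 (adjusted p = 6.11e-06, and adjusted p = 0.109 with an estimated correlation), among them Vim, an intermediate filament protein that leukocytes also express, at 4.60 and the matrix protein Sparc at 1.28, or 2.39 with the processed signals.

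Genes of drug metabolism and fatty acid oxidation fell at 144 h. Of 34 xenobiotic and drug metabolism genes, 20 fell and 1 rose, or 27 and 2 when adjusted over the list alone, with a median of -0.97 (adjusted p = 4.66e-08, and adjusted p = 0.191 with an estimated correlation). The glucuronosyltransferases Ugt2b35 and Ugt2b34 fell by 1.61 (SE 0.24) and 1.41 (SE 0.23), the organic anion exporter Abcc3 fell by 1.28, and the glutathione transferase Gsta1 rose by 1.23. Another probe of Abcc3 gave -0.57, and Ugt2b35 had -2.57 with the processed signals. Of 28 fatty acid oxidation and ketogenesis genes, 14 fell, or 16 when adjusted over the list alone, with a median of -0.56 (adjusted p = 1.58e-05, and adjusted p = 0.18 with an estimated correlation), among them the thioesterase Acot1, which fell by 1.64, or by 1.03 without experiment 3. Of the 4 members with the smallest p, only Acot1 passed when experiment 2 or experiment 3 was left out. The limma adjusted p of the others ranged from 0.0534 to 0.0813 there. Of 30 oxidative phosphorylation genes, 4 fell and 2 rose, or 1 and 1 when adjusted over the list alone, with a median of -0.39 (adjusted p = 0.00107, and adjusted p = 0.316 with an estimated correlation), which was -0.20 without experiment 3. Ndufa4, a subunit of cytochrome c oxidase, was among the risers at 1.18. Of the 4 members of this list with the smallest p, only Ndufa4 passed when experiment 2 or experiment 3 was left out. The others, all lower, had limma adjusted p from 0.0807 to 0.221 there. The markers of leukocytes described above rose in the same RNA.

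Epithelial identity genes moved with them. Of 30 genes of surface colonocytes and ion transport, 11 fell and 4 rose, or 11 and 5 when adjusted over the list alone, with a median of -0.40 (adjusted p = 0.0149, and adjusted p = 0.425 with an estimated correlation), -0.65 without experiment 1 and, with median centring, an adjusted p of 0.0513. The butyrate transporter Slc16a1 fell by 1.83 (SE 0.35) and the carbonic anhydrase Car2 fell by 0.97 (SE 0.14), while Slc51b, a basolateral bile acid transporter, rose by 1.74. Of 19 crypt base and stem cell genes, 9 fell and 1 rose, or 11 and 1 when adjusted over the list alone, with a median of -0.50 (adjusted p = 0.00114, and adjusted p = 0.148 with an estimated correlation). Lgr5, a marker of intestinal stem cells, fell by 1.51 (SE 0.21), Sox9, a crypt transcription factor, fell by 1.17 (SE 0.15), and the growth regulator Myc rose by 1.18. Other probes gave -0.51 for Sox9 and 0.71 for Myc, and with the processed signals Lgr5 had -2.41. Of 17 goblet cell genes, 8 fell and 1 rose, or 9 and 1 when adjusted over the list alone, with a median of -0.57 (adjusted p = 0.00228, and adjusted p = 0.18 with an estimated correlation). The transcriptional repressor Gfi1 was the riser at 1.16, while Spink4, a goblet cell secretory protein, fell by 0.92; without experiments 2 or 3 Spink4 did not pass (adjusted p = 0.0628 and 0.123), with a value of -0.60 without experiment 3. Leukocyte markers rose beside these groups as well.

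The sizes of the largest falls at 144 h rested on experiment 3. Hao2, a peroxisomal hydroxyacid oxidase, fell by 2.63 (SE 0.66, adjusted p = 0.0222), with -1.72, -1.10 and -5.06 in experiments 1, 2 and 3 (standard deviation 2.13). Aadac, an arylacetamide deacetylase, fell by 2.55, the adrenergic receptor Adra2a fell by 2.46, the cytokine Il18 fell by 2.36, the cytochrome P450 Cyp4b1 fell by 2.35 and the carboxylesterase Ces1g fell by 2.33. Slc26a3, the chloride and bicarbonate exchanger of the colon surface, fell by 2.29 (SE 0.46, adjusted p = 0.00905), the tetraspanin Tspan12 fell by 2.15, the membrane scaffold Mpp6 fell by 2.13 and the cGMP-dependent kinase Prkg2 fell by 2.11. Without experiment 3 these 10 genes stood at -1.41, -1.56, -1.59, -1.52, -1.25, -1.23, -1.54, -1.63, -1.40 and -1.43 in the order given. Other probes gave -1.22 for Adra2a and -0.72 for Prkg2, and with the processed signals Aadac had -3.49. With no filter on dim probes Hao2, Cyp4b1, Ces1g and Mpp6 did not pass (adjusted p = 0.0786, 0.0785, 0.0736 and 0.0589). Without experiment 2, Cyp4b1, Ces1g, Slc26a3, Mpp6 and Prkg2 no longer passed (adjusted p = 0.0789, 0.0728, 0.0604, 0.0700 and 0.0560).

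Proliferation, stress and glycolytic genes rose as groups at 144 h, in RNA in which leukocyte markers also rose. Of 26 S phase genes, 14 rose, or 19 when adjusted over the list alone, with a median of 0.71 (adjusted p = 6.69e-06, and adjusted p = 0.316 with an estimated correlation). Cdc6, which loads the replicative helicase, rose by 1.22, or by 1.29 without experiment 2, where it did not pass (adjusted p = 0.0570). Another probe of Cdc6 gave 0.28. Of the 4 S phase members with the smallest p, only Cdc6 passed with median centring or when experiment 3 was left out. None of them passed without experiment 2. Of 29 G2 and mitosis genes, 8 rose, also 8 when adjusted over the list alone, with a median of 0.48 (adjusted p = 0.00233, and adjusted p = 0.497 with an estimated correlation). The 4 G2 members with the smallest p did not pass with median centring (limma adjusted p from 0.0845 to 0.412). They also did not pass without experiment 2 (from 0.101 to 0.260) or without experiment 3 (from 0.0988 to 0.200). Of 24 immediate early and heat shock genes, 13 rose and 1 fell, or 17 and 1 when adjusted over the list alone, with a median of 0.91 (adjusted p = 6.11e-06, and adjusted p = 0.191 with an estimated correlation), among them the transcription factors Egr2 at 3.70 and Nr4a1, which was 8.59-fold higher. Egr3, whose uninfected signal was not well above background on any array, was at least 3.12-fold higher. Of 25 genes of endoplasmic reticulum stress, 10 rose, or 12 with 1 lower when adjusted over the list alone, with a median of 0.52 (adjusted p = 0.00114, and adjusted p = 0.18 with an estimated correlation), among them Chac1, a glutathione-degrading enzyme of the stress response, at 2.05. Of 25 glycolysis and hypoxia genes, 10 rose and 1 fell, or 13 and 1 when adjusted over the list alone, with a median of 0.53 (adjusted p = 0.00311, and adjusted p = 0.316 with an estimated correlation), among them Pfkfb3, which drives glycolytic flux, at 3.54 and the lactate exporter Slc16a3 at 2.80. Of 28 cell death and inflammasome genes, 10 rose and 2 fell, or 13 and 2 when adjusted over the list alone, with a median of 0.39 (adjusted p = 0.0196, and adjusted p = 0.409 with an estimated correlation). The necroptosis genes Ripk3 and Mlkl rose by 1.46 and 1.28, and the genes that fell, named after their values were seen, were the gasdermins Gsdmc by 1.58 and Gsdmc2 by 1.48. Without experiment 1 the glycolysis list, at 0.47, and the cell death list, at 0.22, did not pass (adjusted p = 0.0564 and 0.123).

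Lists that did not pass at 144 h were enteroendocrine cells (median -0.17), tuft cells (0.08), cholesterol synthesis (0.19), lipogenesis (-0.33), p53 targets (-0.05), adhesion and junctions (0.06), pancreatic and gastric genes (0.14) and Paneth cells (0.91, with 6 genes higher and a list adjusted p of 0.0749). The number of genes past the test was 1541 without experiment 2 and 1687 without experiment 3. The split of higher and lower genes depended on the scaling: it was 2338 and 1574 with loess, 1888 and 2320 with the scanner software's processed signals, 1888 and 2322 with the authors' ratios and 1610 and 4010 with median centring, where the median of all genes lay at -0.13 with the processed signals and -0.30 with median centring.

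**Figure D2:**
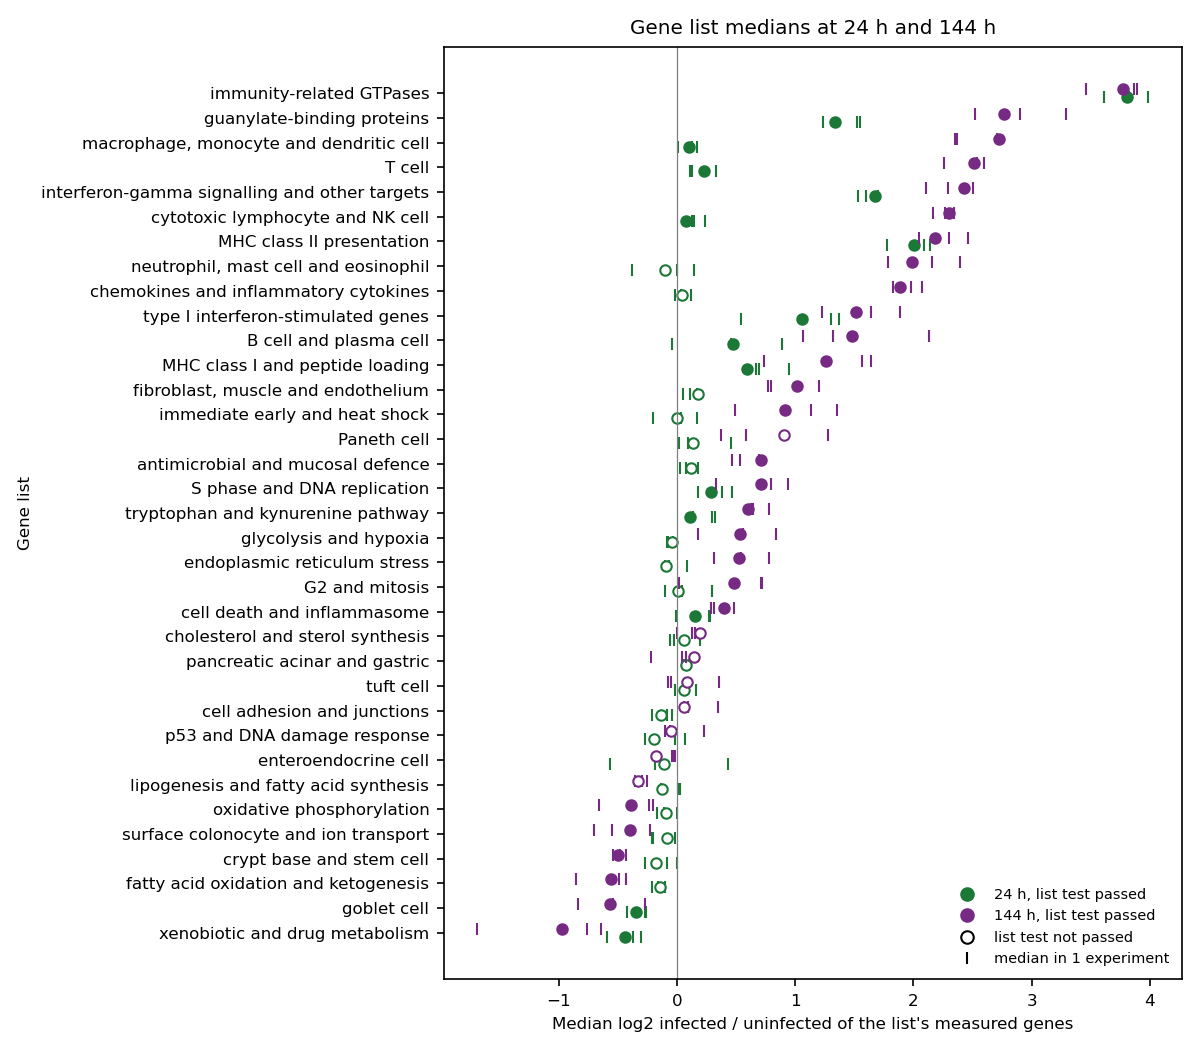
Median log2 ratio of infected over uninfected (x axis) for 35 gene lists (y axis) at 24 h (green) and 144 h (purple), with filled points for lists that passed camera and ticks for the median in each of the 3 experiments. The immunity-related GTPases had medians of 3.81 and 3.77, and the macrophage list had 0.11 and 2.72; with median centring the 24 h medians of the tryptophan, S phase and cell death lists were below 0.

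Comparing the responses at 144 h and 24 h asked which parts of the response grew or receded as the infection went on. Inflammatory and leukocyte genes were far higher at 144 h, while the immunity-related GTPases and Ido1 were already near their later level at 24 h. Ifi202b differed by 5.24 (SE 0.35, adjusted p = 0.000288), Clec7a by 5.17 (SE 0.29, adjusted p = 0.00024), Ccl4 by 4.97 (SE 0.42, adjusted p = 0.000437), Irg1 by 4.54 (SE 0.27, adjusted p = 0.00024) and S100a9 by 4.50 (SE 0.28, adjusted p = 0.000288). With the authors' ratios Ifi202b and Clec7a differed by 6.20 and 7.05. In total 1164 genes differed, 1075 with a higher and 89 with a lower ratio at 144 h.

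Interferon genes did not all follow the same course. Of the 93 genes higher at 24 h, 92 were also higher at 144 h, against 15.0 if the calls at both times were independent (Fisher's exact test, one-sided p = 2.12e-72, with genes not independent). The calls share 1 fit with a common spread per gene, and slides, so they are not independent. Of the 93 genes, 22 differed between the times, all 22 higher at 144 h. Ido1 differed by 0.36 (95% confidence interval -0.43 to 1.14), Irf1 by -0.08 (-0.59 to 0.44), Igtp by 0.15 (-0.52 to 0.82), Irgm1 by 0.11 (-0.45 to 0.67), Iigp1 by -0.33 (-1.32 to 0.67) and Gbp2 by 0.22 (-0.49 to 0.94), none past the test. Ifng, chosen after its value was seen, differed by 2.72 (1.72 to 3.72, adjusted p = 0.00617). The immunity-related GTPase list had a median difference of -0.01 (adjusted p = 0.732), while guanylate-binding proteins were higher at 144 h with a median of 1.71, 6 of 9 members past the test and 7 when adjusted over the list alone (adjusted p = 5.94e-06, and adjusted p = 0.159 with an estimated correlation). MHC class I, with a median of 0.56 (adjusted p = 0.05005), and class II, with 0.27 (0.0684), did not pass, but both did with experiments as blocks (0.0389 and 0.0298). Medians of 0.36 for tryptophan and kynurenine genes, -0.26 for goblet cells and 0.13 for cell death genes did not pass either (adjusted p = 0.737, 0.0998 and 0.503). The other interferon-gamma genes, with 0.32, and the type I genes, with 0.39, passed with 4 and 3 members, or 5 and 5 when adjusted over the list alone (adjusted p = 0.0413 and 0.00915, and adjusted p = 0.519 and 0.551 with an estimated correlation), though not without experiment 1 (0.207 and 0.612, medians 0.29 and 0.21). Neither passed without the 24 h ratio of experiment 1 alone (0.0746 and 0.0892, medians 0.19 and 0.29), and the interferon-gamma list did not with the processed signals (0.0597).

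Leukocyte and inflammatory lists were higher at 144 h than at 24 h. Chemokines and inflammatory cytokines were higher at 144 h with a median difference of 1.93, 18 of 25 members past the test and 20 when adjusted over the list alone (adjusted p = 6.4e-11, and adjusted p = 0.0282 with an estimated correlation). Cytotoxic lymphocyte genes differed by 1.84, with 14 of 19 past the test and 18 when adjusted over the list alone (adjusted p = 6.07e-15, and adjusted p = 0.0282 with an estimated correlation). Macrophage, T cell and neutrophil lists differed by 2.30, 2.11 and 2.12, with 15, 14 and 10 members past the test, or 17, 16 and 11 when adjusted over the list alone (adjusted p = 7.9e-16, 3.73e-13 and 1.78e-12, and adjusted p = 0.0954, 0.114 and 0.159 with an estimated correlation). Immediate early genes, with 0.74, endoplasmic reticulum stress genes, with 0.64, and glycolysis genes, with 0.57, also had higher medians at 144 h, with 7, 4 and 4 members past the test, or 11, 6 and 6 when adjusted over the list alone (adjusted p = 2.72e-05, 0.000348 and 0.0026, and adjusted p = 0.359, 0.239 and 0.458 with an estimated correlation).

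Some epithelial and metabolic lists had lower medians at 144 h than at 24 h, though few of their members passed the test on their own. Xenobiotic metabolism genes differed by -0.60, fatty acid oxidation genes by -0.36, crypt base genes by -0.40 and oxidative phosphorylation genes by -0.29. In the same order, the counts of lower members past the test were 1, 1, 2 and 0, and those of higher members 1, 0, 0 and 1. Adjusted over the list alone they were 0, 0, 4 and 0 lower and 1, 0, 0 and 1 higher. The lists passed as groups (adjusted p = 0.000581, 0.000681, 0.00735 and 0.0105, and adjusted p = 0.517, 0.359, 0.244 and 0.519 with an estimated correlation). With fry the xenobiotic, fatty acid oxidation and oxidative phosphorylation lists did not pass (adjusted p = 0.281, 0.117 and 0.264). Without experiment 3 the xenobiotic median was -0.19, the crypt base median -0.25 and the oxidative phosphorylation median -0.02, the last no longer past the test (adjusted p = 0.173). Without experiment 1 the crypt base list did not pass (0.0870), and with the processed signals the oxidative phosphorylation list did not (0.0653). Slc26a3 differed by -2.80 (SE 0.65, adjusted p = 0.037), which did not pass with experiments as blocks (0.0586). Tcf7l1, a transcription factor of the Wnt pathway, differed by -1.88 (SE 0.37), the linker histone H1f2 by -1.86 (SE 0.45), the lysosomal ubiquitin ligase Rnf152 by -1.84 (SE 0.38) and the zinc finger protein Zfp704 by -1.84 (SE 0.37). Without experiment 2 these 5 genes had adjusted p = 0.219, 0.182, 0.329, 0.109 and 0.165, and without experiment 3 they had 0.0806, 0.0722, 0.192, 0.0816 and 0.0745, with Slc26a3 at -1.71 and Rnf152 at -1.21. None of them passed on arrays with infected RNA in Cy5 alone (0.183, 0.133, 0.0631, 0.118 and 0.195) or with no filter on dim probes (0.126, 0.0646, 0.129, 0.0766 and 0.0659). The count of genes that differed was 428 without experiment 2, 601 without experiment 3 and 688 without the 24 h ratio of experiment 2 alone, and with median centring the split was 894 higher and 211 lower.

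**Figure D3:**
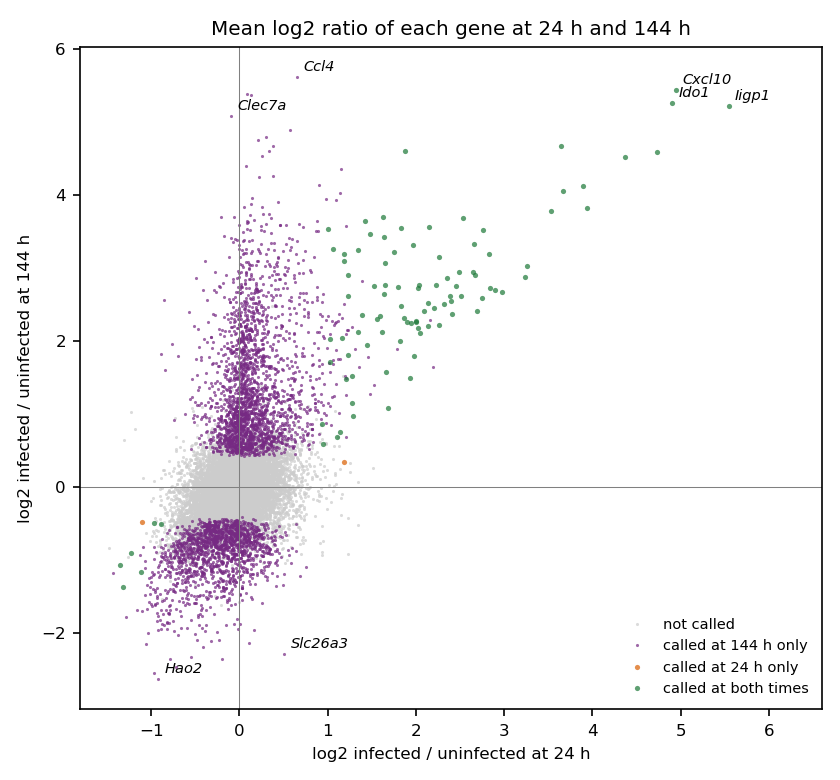
Log2 ratio of infected over uninfected at 24 h (x axis) against 144 h (y axis) for 14498 genes, with purple points for genes past the test at 144 h only, orange at 24 h only, green at both times and grey at neither. Ido1 and Iigp1 have high values at both times, and Clec7a and Ccl4 lie far above the diagonal with differences of 5.17 and 4.97.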

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

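The tests on metabolic genes below were chosen after the result was seen, and the comparison with other splits of the samples was planned.

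The response at 144 h differed from that at 24 h for 1164 genes and 22 gene lists, each by the limma or camera test of the difference itself. With an estimated correlation only 2 of the 22 lists passed, chemokines and cytotoxic lymphocytes (adjusted p = 0.0282 each). Lists of immune cells were higher at 144 h, with median differences (log2) of 2.30 for macrophages, monocytes and dendritic cells, 2.12 for neutrophils, mast cells and eosinophils, 2.11 for T cells, 1.84 for cytotoxic lymphocytes and NK cells and 0.98 for B and plasma cells. With an estimated correlation the macrophage, neutrophil, T cell and B cell lists had adjusted p = 0.0954, 0.159, 0.114 and 0.519. Chemokines and inflammatory cytokines differed by 1.93, guanylate-binding proteins by 1.71, antimicrobial genes by 0.70, type I interferon genes by 0.39 and other interferon-gamma genes by 0.32. Fibroblast, muscle and endothelium genes differed by 0.85, immediate early genes by 0.74, endoplasmic reticulum stress genes by 0.64, glycolysis genes by 0.57, S phase genes by 0.40, G2 and mitosis genes by 0.38 and adhesion genes by 0.29. Xenobiotic metabolism genes differed by -0.60, crypt base genes by -0.40, fatty acid oxidation genes by -0.36, surface colonocyte genes by -0.32 and oxidative phosphorylation genes by -0.29.

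Of the lists that the report does not compare between the times, the fibroblast (adjusted p = 4.02e-05, with 3 members past the test), B cell (0.00224, 0 members), antimicrobial (0.0162, 5 members), adhesion (0.0197, 5 members), S phase (0.0301, 0 members), G2 and mitosis (0.0334, 0 members) and surface colonocyte (0.0402, 1 member) lists passed. In the same order, they had adjusted p = 0.159, 0.519, 0.443, 0.244, 0.622, 0.664 and 0.573 with an estimated correlation. Adjusted over the list alone, the counts of members higher at 144 h were 7, 6, 10, 6, 0, 0 and 0. At an unadjusted limma p under 0.05, 8 B cell, 4 S phase and 5 G2 genes were higher at 144 h. With median centring the S phase and G2 lists did not pass (adjusted p = 0.0532 and 0.0515), and with the strict filter on dim probes the antimicrobial list did not (0.735). Without experiment 1 the B cell list, at 0.41, and the adhesion list, at 0.21, did not pass (adjusted p = 0.0744 and 0.123). Without experiment 3 the S phase list, at 0.13 (0.853), the G2 list, at 0.44 (0.0752), and the colonocyte list, at -0.19 (0.102), did not pass. Without experiment 2 the G2 list, at 0.19 (0.643), and the colonocyte list, at -0.23 (0.124), did not.

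Among single genes, the difference was 5.24 for Ifi202b, 5.17 for Clec7a, 4.97 for Ccl4, 4.54 for Irg1 and 4.50 for S100a9. It was -2.80 for Slc26a3, -1.88 for Tcf7l1, -1.86 for H1f2, -1.84 for Rnf152 and -1.84 for Zfp704, and none of these last 5 passed without experiment 2 (adjusted p from 0.109 for Rnf152 to 0.329 for H1f2).

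Of the 10 splits of the 6 ratios into 3 and 3, only 1, the real one, gave as many as 1164 genes, and the highest of the others gave 0. Of the 4 ways of turning the sign of the 3 ratios, 1 gave 100 genes at 24 h and 1 gave 3912 at 144 h, the real one each time, and the highest of the others gave 0. These splits are too few for a share under 0.05. Turning the sign of a ratio or mixing the times also adds any real change to the spread of the genes that carry it. Few calls were therefore likely in advance, and the counts of 0 lend the real calls no support.

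Genes of xenobiotic metabolism and fatty acid oxidation were lower at 144 h, with a median of -0.82 over 62 genes. If a smaller epithelial share of the RNA were the whole cause, genes expressed across the epithelium would be lower alike, but 25 such genes had a median of -0.08, which lay 0.74 (95% interval 0.43 to 0.93) above the metabolic genes. The loess step as the cause is argued against by the median of -1.15 with median centring, where all genes had a median of -0.30. Median centring is itself a normalization within arrays, so an effect common to both ways of scaling was not tested. The interval resamples genes and not experiments. What stays open is a smaller epithelial share as a part of the cause, and a change in which epithelial cells were released or in what they express. A candidate explanation of the last kind is a loss of the metabolic programme of the absorptive cells, for which no separate test was run. The size of the fall differed between experiments, with xenobiotic medians of -0.76, -0.64 and -1.69.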

How the results depend on the processing

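Leaving out the 24 h ratio of experiment 2 or 1 alone was chosen after seeing the data; the other alternatives were planned. Of the named genes that passed, 25 of 40 at 24 h, 97 of 127 at 144 h and 5 of 10 between the times kept their direction and their side of the threshold in every alternative that gave them a value. Of the 32 that did not pass at 24 h, 23 did not pass in any alternative, and 20 of these kept their sign. No list of 15 at 24 h, but 2 of 27 at 144 h and 2 of 22 between the times, did so. The strict filter on dim probes gave a value to only 65 of all 72 named genes at 24 h, 100 of 128 at 144 h and 5 of 10 between the times, and to 14, 25 and 20 of these lists. With an estimated correlation 0, 2 and 2 lists passed, and with fry 8, 29 and 13. At 24 h the xenobiotic, goblet cell, S phase, cell death, T cell, B cell and macrophage lists passed camera but not fry. At 144 h the G2 and surface colonocyte lists did so. Between the times they were xenobiotic, fatty acid oxidation, oxidative phosphorylation, S phase, G2, surface colonocyte, B cell, type I interferon and other interferon-gamma lists. At an adjusted p under 0.01 the genes numbered 63, 1805 and 664, fewer by construction, and 1891 changed at least 2-fold at 144 h. The strict filter on dim probes left fewer genes to test and gave 2411 at 144 h and 367 between the times. All 12 arrays with a dye term gave 226 genes at 24 h, and the cause was not tested. Leaving out each experiment gave 37 to 109 genes at 24 h, 1541 to 4744 at 144 h and 428 to 1605 between the times, and 11 to 19, 24 to 29 and 17 to 23 lists, with fewer samples in each fit; the lowest gene counts were without experiment 2, and without experiment 3 they were 58, 1687 and 601. Without the 24 h ratio of experiment 2 alone, 52 genes passed at 24 h and 688 between the times. With experiments as a replicate block, 85, 4222 and 1214 genes and 15, 26 and 24 lists passed. Malat1 at 144 h, added after the value of Xist was seen, did not pass at 0.16, the highest value of 4 probes that ranged from -0.88 to 0.16. It ranged from -0.85 without experiment 1, where it passed with the opposite sign (adjusted p = 0.022), to 0.76 without experiment 2. Its value in experiment 1 was 2.17. Signal over background limits the fold of genes near background in uninfected RNA, such as Gbp6, above background on 1 of 6 uninfected arrays at 24 h, and Egr3.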

Other observations

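Of the tests in this part, that on Malat1 was written before its result was seen; the other tests on class II genes and Xist, the gene families and the single genes were chosen after the values were seen.

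Families of genes that share a symbol stem also moved, but they overlap with genes and lists described above. Clec7a, Ces1g, Ugt2b34 and Ugt2b35 belong to the Clec, Ces and Ugt families, so these families are not separate evidence. Apolipoprotein L genes (Apol) had a median of 1.78 over 6 genes at 24 h, 5 of them higher (camera adjusted p = 7.07e-20 over 306 families, and adjusted p = 0.814 with an estimated correlation), and of 2.26 at 144 h, again 5 higher (adjusted p = 5.03e-06, and adjusted p = 0.626 with an estimated correlation). At 144 h all 7 lymphocyte GTPases of the Gimap family rose (median 2.38, adjusted p = 1.4e-14), as did all 8 NK cell receptors of the Klra family (2.19, adjusted p = 6.45e-05) and 10 of 16 C-type lectins of the Clec family, 2 of which fell (1.81, adjusted p = 4.02e-18). These had adjusted p = 0.626, 0.774 and 0.626 with an estimated correlation. Carboxylesterases (Ces) fell in 10 of 10 cases with a median of -1.54, UDP-glucuronosyltransferases (Ugt) in 7 of 8 with -1.51, glutathione transferases of the mu class (Gstm) in 5 of 7 with -1.05, and homeobox genes of the Hoxb cluster in 5 of 7 with -0.92. Their adjusted p was 0.000886, 0.00371, 0.0262 and 0.0263, and adjusted p = 0.774 with an estimated correlation for each of the 4. Under the other scalings and without each experiment no family median changed sign: Apol ranged from 1.46 to 1.91 at 24 h, Gimap from 2.08 to 2.81, Klra from 1.60 to 3.31, Ces from -1.92 to -1.04, Ugt from -2.34 to -1.18, Gstm from -1.44 to -0.86 and Hoxb from -1.34 to -0.62.

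Some single genes outside the rule for named genes also changed at 144 h. Reg3b and Reg3g, secreted antibacterial lectins, rose by 4.25 (adjusted p = 0.00416) and 2.63 (0.00586), and the matrix metalloproteinases Mmp10 and Mmp13 by 2.43 and 2.13, with the urokinase receptor Plaur at 2.16. With the scanner software's processed signals Mmp10 and Mmp13 rose by 3.59 and 5.16. In the tuft cell list, which did not pass, members went both ways. Alox5, Alox5ap, Ptgs1 and Plcg2, which leukocytes express as well, rose, the last 3 by 2.05, 1.38 and 1.88. Dclk1, Trpm5 and Gng13, a kinase and signalling proteins typical of tuft cells, fell by 0.83, 0.58 and 0.72. These 3 did not pass without experiment 2 (adjusted p = 0.148, 0.182 and 0.208), nor did Trpm5 and Gng13 without experiment 3 (0.115 and 0.191). With the processed signals Dclk1, Trpm5 and Gng13 had -1.60, -1.10 and -1.26. The 3 measured genes of the untested erythroid list had medians of 0.42 at 24 h and -0.10 at 144 h, and its platelet chemokine Pf4 rose by 2.73 at 144 h.

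Class II genes were higher at 24 h, when leukocyte markers had moved little. If more antigen-presenting cells with unchanged class II per cell were the cause, their markers would be as high, but 35 such markers had a median of 0.15, which lay 1.86 below that of the 13 class II genes with a 95% interval of -0.03 to 2.23. The interval includes 0, so this cannot be told apart from induction within cells already present, which may include epithelial cells. A dye or labelling bias as the cause is argued against, since it would turn the sign with the dye, but the median was 1.75 (95% interval 0.19 to 2.30) on the 3 arrays with infected RNA in Cy3 and 2.02 on the 3 with it in Cy5; the share of the genes above 0 on all 6 arrays, 61.5% (8 of 13), missed the bound set for it and decides nothing. Macrophages, dendritic cells and B cells were not removed by any sort that the labels describe.

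Xist, the RNA that coats the inactive X chromosome, was lower at 144 h (-1.88, SE 0.56, adjusted p = 0.0416), with -0.21, -2.25 and -3.20 in experiments 1, 2 and 3 (standard deviation 1.53, while the SE pools both times) and with 4 probes that ranged from -1.91 to 0.01. It did not pass without experiment 2 (-1.70, adjusted p = 0.233) or experiment 3 (-1.23, 0.179), nor with experiments as blocks (0.0633) or on arrays with infected RNA in Cy3 alone (0.129). At 24 h Xist had -1.28, -0.14 and 0.97 in experiments 1, 2 and 3. The dye-swapped arrays of experiment 2 at 24 h gave -2.34 with infected RNA in Cy5 and 2.06 with it in Cy3. On these arrays Malat1 gave -1.245 and 2.093 in the same order, so both RNAs turned sign with the dye there. Mice of different sex in the arms stay open: Y-linked probes (8 probes of 5 genes) were well above background on 0 of 6 arrays at 144 h, but on at most 1 of 6 at 24 h as well, so nothing shows that they would report male RNA. The Xist probe used was itself well above background in infected RNA on 6 of 6 arrays at 144 h. A mix of sexes among the animals of an arm, whose number is not given, would leave such a signal too. Lower recovery of nuclear RNA from infected cells was tested with Malat1, another nuclear RNA, and could not be decided. Malat1 had a mean of -0.85 in experiments 2 and 3 at 144 h, against -2.72 for Xist. Its value meets neither bound set for that test, and in experiment 1 it was 2.17. Other Malat1 probes had -0.47, -1.32 and -0.38 in experiment 2, -1.22, -1.96 and -1.55 in experiment 3, and 0.96, 0.65 and 1.35 in experiment 1. The probe at -1.32 and -1.96 would meet the bound for this cause, so the outcome of the test depends on the probe. Different sex, lower recovery of nuclear RNA and a change in which cells were released cannot be told apart with the values at hand.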
